A study of Mus musculus with 44 samples.

How the data were processed

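Alveolar macrophages of C57BL/6 mice were profiled by RNA-seq and ATAC-seq at postnatal day 4 (P4) and in adults of 8 weeks (8W), in 44 samples: 28 RNA-seq libraries and 16 ATAC-seq libraries. Per the labels, 12 RNA-seq libraries and 8 ATAC-seq libraries came from cells taken directly (0h) or after 20 h in culture with fetal serum and the macrophage growth factor M-CSF. The others came from mice given PBS or bacterial lipopolysaccharide (LPS) into the nose and sampled after 2 h. The 12 in vitro RNA-seq libraries formed 4 groups of 3 (P4 0h, P4 20h, 8W 0h, 8W 20h), and the 16 ATAC-seq libraries formed 8 groups of 2. Column names gave the group of each in vitro library and no replicate number. Replicate numbers used below follow the order of the column codes within a group and may differ from those of the sample titles. The 16 in vivo RNA-seq libraries are in a table whose 80 columns could not be matched to groups from their names, so that table was not used here and no LPS effect on expression was analysed here.

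Per the submitters' processing notes, the tools were Trimmomatic 0.36, STAR 2.5.3a, RSEM 1.3.0 and Bowtie2 (version not given in the sources used here), with genome build mm10. The deposited in vitro RNA-seq table holds RSEM expected counts per gene, which are not normalized. Of its 60 columns of values, 12 were used, 1 of expected counts per library, and 48 were not. Per the labels' protocols the RNA kit was stranded, but the strand setting of the counting is not given in the sources used here, so antisense and overlapping genes are uncertain. Per the file headers, each ATAC-seq peak list was merged with HOMER from peaks passing an irreproducible discovery rate (IDR) analysis of 2 libraries. The peak caller is not given in the sources used here. The score of each peak is the authors', with 540 standing for an IDR of 0.05, 830 for 0.01, and 1000 the highest score the scale allows. Read depth is unknown for the ATAC-seq lists, and there is 1 list per pair of libraries, so no replicate test of accessibility was possible.

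The in vitro table has 54446 genes, of which 54409 identifiers (99.9%) were paired with a symbol. Total expected counts per library ran from 28987690 to 45455367. No replicate pair agreed within sampling noise (chi-square per degree of freedom between 2.72 and 14.94), so each library was counted as 1 sample. No label used here states that the libraries of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

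Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr, 1 factor with 4 groups, and the quasi-likelihood test (glmQLFit, glmQLFTest) on contrasts. Of all genes, 15939 passed the filter. P-values were adjusted by Benjamini-Hochberg over all tested genes, and a gene was called at an adjusted p under 0.05. The 5 contrasts were culture at P4, culture at 8W, the difference of these 2 culture effects, P4 minus 8W at 0h, and P4 minus 8W at 20h. Log2 changes come from edgeR with their standard error (SE), a value beside a gene without a unit is its log2 change, and CPM values are TMM-scaled group means with the SD over 3 libraries.

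The 17 gene lists were early inflammatory cytokines and chemokines, NF-kB feedback and target genes, interferon-stimulated genes, components of LPS and Toll-like receptor (TLR) signalling, alveolar macrophage identity, interstitial macrophages and monocytes, cell cycle, cholesterol biosynthesis, targets of the oxysterol receptor LXR with fatty acid synthesis, glycolysis and hypoxia, NRF2 antioxidant genes, immediate-early and heat-shock genes, MHC class II with co-stimulation, phagocytic and scavenger receptors, matrix remodelling, fetal and imprinted growth genes, and TGF-beta with GM-CSF signalling. Marker lists covered neutrophils, alveolar type 2 epithelium, airway and type 1 epithelium, endothelium, fibroblasts and smooth muscle, T and NK cells, B cells, eosinophils and basophils, dendritic cells, erythroid cells, and sex-linked genes. All lists, tests and alternatives were fixed before the data were examined, except those named as added later. Lists were tested with camera in limma 3.58.1, with a preset inter-gene correlation of 0.01 and adjustment over the lists, and again with an estimated correlation. Unless stated otherwise, the adjusted p of a list is the camera value with the preset correlation.

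Genes named in the text followed a fixed rule. For each contrast these were the 6 largest rises and 6 largest falls among called genes with a CPM of at least 10 in the higher group and no overlap between groups (no overlap rule for the difference of effects), without predicted gene models. Added to these were up to 4 members per list with the smallest adjusted p and a CPM of at least 5, and 10 fixed genes (among them Pparg, Fabp4, Car4, Siglecf, Marco, Chil3, Mki67, Cd14 and Tlr4). Some genes chosen by these rules are not reported here. Marker genes are given for their lists. In culture, the largest adjusted p of a gene called under this rule was 2.5e-06 at P4 and 0.0016 at 8W by edgeR. It was 0.0051 for the difference of the culture effects, 0.008 for age at 0h and 0.044 for age at 20h. Ear1, Chil3, Ces2c, Spag11b, Hba-a2, Scd1, Scd2, Trim30a, Oas1a and Ifit3 belong to families with close copies, among which RSEM can divide reads, so their values are uncertain.

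The share of an age difference kept in culture was the slope through the origin of the log2 difference at 20h on that at 0h over genes called at 0h, with a jackknife SE over the 12 libraries. The planned counterpart of this share with genes chosen from the in vivo table was not run. The jackknife SE pools 4 groups, and each library left out also changes the genes that pass the filter, so it does not measure replicate spread alone. Peak lists were compared with bedtools 2.31.1, a peak counting as found in another list at an overlap of at least 1 bp, with 95% Wilson intervals that cover counting error only. Peaks were set against expression by counting genes with a peak of 1 list and not of the other within 20 kb of the gene span. Gene positions came from the RefSeq table of GRCm38.p6, the assembly behind mm10, for 14730 of the 15939 tested genes (92.4%). That table carries no strand, so the whole gene span replaced the planned distance to the gene start. Shares were compared by Fisher's exact test, two-sided, across genes, which are not independent replicates, and 0.5 was added to each cell for an odds ratio with an empty cell. For LPS against PBS the 17 fixed lists were used in place of called genes, as 68 tests, with 10000 random lists matched on the number of differing peaks near each gene as a second reference. Both were added after the data were seen. Motif content was not analysed here for want of a genome sequence.

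Alternatives were RLE scaling, DESeq2 1.42.0, no low-count filter, a filter at a CPM of 5, only the 2 groups compared, and each of the 12 libraries left out in turn. A fit of limma on log2(CPM + 1) with plain library totals was added after the data were seen. It took the place of a planned fit on TPM, which had been run and seen, because columns without replicate numbers were taken for 1 measure per library only. For lists they were an estimated correlation and fry. For peaks they were an IDR of 0.01, a reciprocal overlap of 50%, lists of equal size drawn at the top of the score (13297 peaks, ties at random, 5 draws), and windows of 5 and 100 kb. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1 were used for tables and exact tests.

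Each step was tested on simulated data first. Among genes given a 2-fold change, the edgeR step recovered 66% for culture at P4 (15330 genes), 70% for culture at 8W (15343 genes), 66% for the difference of the culture effects (15313 genes), and 66% for age at 0h (15327 genes) and at 20h (15322 genes). It made between 6 and 8 false calls per contrast. For a list of 25 genes raised 1.5-fold in simulated culture at P4 (15939 genes), camera gave an adjusted p of 2.5e-48, or 1.7e-05 with an estimated correlation, and called 0 of 100 random lists either way. Genes were simulated independently of each other, so this says nothing on false calls in lists whose genes move together. The peak step (14730 genes) found a peak at 80.0% of 200 genes, of which 150 had been given one, and gave an odds ratio of 18.23 for these and 1.0 for random genes.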

Results

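Alveolar macrophages live on the air side of the lung, where they clear surfactant and inhaled particles, and at P4 they have only just filled that niche. The comparisons below address what these cells express once taken out of the lung, and which differences between neonatal and adult cells remain in a shared culture medium. Total expected counts per library were 45455367, 44625819 and 28987690 at P4 0h, and 41225197, 36404711 and 38887672 at 8W 0h. At 20h they were 32094712, 38478837 and 34715048 at P4, and 33953651, 39345053 and 41693272 at 8W. Culture separated the libraries along the first principal component (54.6% of the variance), from between -104.54 and -102.62 at P4 0h and between -34.35 and -31.82 at 8W 0h to between 46.11 and 50.83 at P4 20h and between 87.02 and 89.71 at 8W 20h. All adult libraries carried one column code and all P4 libraries another, so any batch between them cannot be told apart from age. The same holds for sex, since Xist was nearly absent from adult libraries and high at P4, where Y-linked genes were present too. The freshly taken P4 libraries also held transcripts typical of other lung cells: the surfactant gene Sftpc stood between 391 and 429 CPM at P4 0h and between 32.7 and 35.1 at 8W 0h, and the collagen gene Col3a1 between 124 and 127 against 1.52 and 3.16. At P4 20h Sftpc had dropped to between 10.6 and 13.5 CPM and Col3a1 to between 2.28 and 4.22.

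Cultured for 20 h, neonatal macrophages raised NRF2 antioxidant genes, while 17 of 23 immediate-early and heat-shock genes fell. Nqo1, a quinone reductase driven by the stress sensor NRF2, rose from 0.836 ± 0.135 to 25.9 ± 1.09 CPM (mean ± SD, n = 3 libraries per group, as in every CPM mean that follows). Fosb, a transcription factor switched on within minutes of a stimulus, dropped from 119 ± 2.18 to 0.189 ± 0.0849 CPM. Car4, the carbonic anhydrase that marks macrophages of the alveolus, dropped from 528 ± 10.5 to 2.64 ± 0.446 CPM. Of 15939 tested genes, 10610 were called by edgeR's quasi-likelihood test, 5145 higher and 5465 lower at 20h, with 1184 and 2476 of these at least 2-fold. The rises made up 48.5% of the called genes but 26.4% with limma on log2(CPM + 1), where the median change of all genes was -0.20. Among genes with a mean CPM of at least 5 at 20h, a choice that favours rises, the balance turned to 4293 higher and 2906 lower. Of these 638 and 375 changed at least 2-fold. The named genes had a median SE of 0.07 on the log2 scale.

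The largest rises at P4 under the naming rule were Hpse (log2 change 6.54 ± 0.06 SE), which cleaves heparan sulfate, Slc11a1 (6.45), a metal pump of the phagosome, and Pla2g7 (6.43), a secreted phospholipase. Of 16 NRF2 genes 15 rose and 0 fell (adjusted p = 2.6e-09, and 0.019 with an estimated correlation), including the cystine importer Slc7a11 (4.33), Srxn1 (2.97) and the peroxidase Prdx1 (2.49). Interferon-stimulated genes rose, 22 of 26 with 1 fall, or 22 and 2 adjusted over the list alone (median 1.83, adjusted p = 7.4e-05, but 0.4 with an estimated correlation), among them the antiviral Bst2 (1.53), Oas1a (1.52) and the RNA sensor Ddx58 (0.99). NF-kB feedback and target genes rose at 16 of 25 and fell at 2 (median 0.56, adjusted p = 0.00069, but 0.21 with an estimated correlation), such as the brakes Tnip1 (1.10), Bcl3 (1.69) and Irak3 (0.87). Immediate-early and heat-shock genes fell, 17 of 23 with 4 rises (adjusted p = 7.6e-05, but 0.1 with an estimated correlation). The phosphatase Dusp1 changed by -4.79 and Fos by -3.84 while Atf3 rose by 2.63. Alveolar macrophage identity genes fell at 20 of 30 and rose at 9 (median -0.99, adjusted p = 0.0022, but 0.16 with an estimated correlation). Siglecf, a sialic acid receptor, fell by 2.77 and the ribonuclease gene Ear1 by 4.22, whereas the lipid carrier Fabp4 rose by 4.40, and Pparg, the nuclear receptor that specifies the cells, fell by 0.81. Cell cycle genes fell at 34 of 35 and rose at 0 (median -0.63, adjusted p = 3e-08, but 0.11 with an estimated correlation). Cholesterol biosynthesis genes fell at 17 of 23 and rose at 1 (median -0.33, adjusted p = 0.00089, but 0.28 with an estimated correlation). MHC class II genes, which present antigen, fell at 9 of 12 and rose at 3 (adjusted p = 0.018, but 0.11 with an estimated correlation). H2-Aa changed by -2.34 and H2-Eb1 by -2.92. Fetal and imprinted genes fell at 8 of 14 and rose at 3 (median -2.60, adjusted p = 0.048, but 0.11 with an estimated correlation). The imprinted Meg3 changed by -7.44. Fibroblast markers fell too (median -5.35), and which cells the fetal transcripts came from was not measured. Glycolysis genes rose at 12 of 20 and fell at 5, which turned to 9 and 9 with limma on log2(CPM + 1) (adjusted p = 0.04, but 0.21 with an estimated correlation). The pyruvate kinase Pkm changed by 1.27.

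Several lists moved both ways in culture at P4. Inflammatory cytokines rose at 7 of 19 and fell at 8 (adjusted p = 0.46), with falls of Il1b (-2.79), Osm (-3.41) and Il1rn (-2.29). TLR signalling genes rose at 10 of 21 and fell at 8 (adjusted p = 0.48), which turned to 8 and 11 with limma on log2(CPM + 1). The LPS co-receptor Cd14 fell by 2.45 and Tlr4 by 0.84, while Tlr1 rose by 3.47. Interstitial macrophage genes rose at 6 of 17 and fell at 7 with a median of 0.18 and a mean of -0.65 (adjusted p = 0.72), and Ms4a7 rose by 2.01. Phagocytic receptors rose at 8 of 17 and fell at 8, or 5 and 9 with limma on log2(CPM + 1) (median -0.02 but an upward test, adjusted p = 0.96). Among them the complement receptor Itgam rose by 2.82. Matrix genes rose at 8 of 19 and fell at 11 with a median of -0.45 and a mean of 0.11 (adjusted p = 0.86). Among them Gpnmb, a lysosomal glycoprotein, climbed from 253 ± 1.22 to 5180 ± 31.9 CPM. LXR targets and TGF-beta genes each rose at 4 of 15 and fell at 8 (adjusted p = 0.32 for both). The LXR list included the desaturase Scd1 at -4.51, and the TGF-beta list Cish at -3.18 and Socs2 at -2.98, both targets of GM-CSF.

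Markers of other lung cells fell with culture at P4. All 9 endothelial and all 10 fibroblast genes fell (adjusted p = 6e-06 and 9.6e-06, and 0.019 and 0.037 with an estimated correlation), as did 8 of 8 B cell genes (adjusted p = 0.00036, and 0.037 with an estimated correlation). Type 2 cell genes fell at 8 of 10 with 1 rise (adjusted p = 0.00068, but 0.11 with an estimated correlation), and airway and type 1 genes fell at 8 of 11 with 2 rises (adjusted p = 0.014, but 0.1 with an estimated correlation). Erythroid genes fell at 5 of 5 (adjusted p = 0.014, but 0.11 with an estimated correlation), T and NK genes at 8 of 10 with 1 rise (adjusted p = 0.037, but 0.11 with an estimated correlation), and eosinophil genes at 3 of 3 (adjusted p = 0.049, but 0.13 with an estimated correlation). Neutrophil genes fell at 7 of 12 and rose at 2 (adjusted p = 0.32), and dendritic cell genes fell at 6 of 8 and rose at 1 (adjusted p = 0.083). Sex-linked genes rose at 3 of 5 and fell at 1, or 3 and 2 adjusted over the list alone, which turned to 1 and 2 with limma on log2(CPM + 1) (adjusted p = 0.72). At 20h 3 of the 10 type 2 genes and 2 of the 9 endothelial genes were at 5 CPM or more at each age, as were 4 of 11 airway and type 1 genes and 4 of 12 neutrophil genes at P4 and 1 and 3 at 8W, and whether macrophages or remaining other cells gave these was not tested. Cldn5 (-9.06), Ptprb (-8.01), Scn7a (-8.50) and Slc34a2 (-8.65), genes typical of endothelium, other stromal cells or type 2 cells, were the largest falls beside Fosb and Car4 under the naming rule. Which cells their transcripts came from was not measured.

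Adult macrophages in the same medium moved most called genes in the same direction, while single genes such as Mmp12 and Sqle responded higher than at P4. Mmp12, the macrophage elastase, rose from 3.86 ± 0.52 to 888 ± 41.5 CPM. Sqle, a rate-setting enzyme of cholesterol synthesis, rose from 31.9 ± 1.09 to 73.3 ± 5.05 CPM, where at P4 it declined from 41.4 ± 1.19 to 30 ± 1.32. Car4 dropped from 458 ± 5.61 to 2.34 ± 0.455 CPM and Fosb from 117 ± 6.49 to 0.113 ± 0.0703. By edgeR 10413 genes were called, 4857 higher and 5556 lower at 20h, with 1215 and 2326 at least 2-fold. Rises made up 46.6% of the called genes, but 27.0% with limma on log2(CPM + 1), where the median change of all genes was -0.18. With a mean CPM of at least 5 at 20h required, which favours rises, 4085 were higher and 3321 lower. Of these 662 and 561 changed at least 2-fold. Genes called in both ages rose together at 3610 and fell together at 3832, where 1568 and 1905 would be expected for unrelated calls, and moved in opposite directions at 331 and 263.

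The largest adult rises under the naming rule were Fam20c (8.04 ± 0.11 SE), a kinase of secreted proteins, Mmp12 (7.84), Vsig8 (7.44), Pla2g7 (7.37), Slc11a1 (7.21) and the aminopeptidase Anpep (6.84). Cholesterol biosynthesis genes rose at 21 of 23 and fell at 1, or 22 and 1 adjusted over the list alone (median 0.66, adjusted p = 6e-07, but 0.2 with an estimated correlation), including the regulator Srebf2 (0.92), Fdps (1.04) and Dhcr7 (0.96). NRF2 genes rose at 15 of 16 (median 1.69, adjusted p = 5.7e-10, and 0.022 with an estimated correlation). Slc7a11 changed by 4.00, Srxn1 by 3.30 and Txnrd1 by 1.86. Cell cycle genes fell at 33 of 35 and rose at 2 (median -1.41, adjusted p = 1.2e-11, but 0.13 with an estimated correlation). The proliferation marker Mki67 changed by -2.28 and the cyclin Ccnb2 by -3.19. Immediate-early genes fell at 17 of 23 and rose at 2, or 3 adjusted over the list alone (adjusted p = 0.00017, but 0.14 with an estimated correlation). Dusp1 changed by -5.82. Interferon-stimulated genes rose at 15 of 26 and fell at 2 (median 0.63, adjusted p = 0.016, but 0.59 with an estimated correlation). Irf7 changed by 2.10 and Oas2 by 2.34. Identity genes fell at 20 of 30 and rose at 9 (median -0.96, adjusted p = 0.016, but 0.28 with an estimated correlation): Fabp1 fell by 5.08, Krt19 by 4.25 and Chil3 by 1.92, while Fabp4 rose by 2.96. MHC class II genes fell at 10 of 12 and rose at 1 (adjusted p = 0.0082, but 0.11 with an estimated correlation). H2-DMb2 changed by -3.08. Glycolysis genes rose at 12 of 20 and fell at 6 (median 0.58, adjusted p = 0.016, but 0.2 with an estimated correlation). Pgam1 changed by 2.31.

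In adult cells 9 further gene lists were not called by camera, while 4 lists of markers were. Inflammatory cytokines rose at 6 of 19 and fell at 9 (adjusted p = 0.41), with Il1b at -3.65 and Il1a at 1.25. NF-kB genes rose at 12 of 25 and fell at 7, which turned to 11 and 12 with limma on log2(CPM + 1) (adjusted p = 0.21). TLR genes rose at 8 of 21 and fell at 11 (adjusted p = 0.41), with Cd14 at -3.63 and Tlr2 at -1.75. Phagocytic receptors rose at 7 of 17 and fell at 9 (adjusted p = 0.85), among them Itgam at 5.13 and the anaphylatoxin receptor C5ar1 at -4.13. Matrix genes rose at 10 of 19 and fell at 7 (adjusted p = 0.25), with Mmp14 at 5.50, and Gpnmb climbed from 474 ± 9.07 to 7860 ± 365 CPM. Interstitial macrophage genes rose at 4 of 17 and fell at 8 (adjusted p = 0.61). LXR targets rose at 4 of 15 and fell at 9 (adjusted p = 0.13), with the cholesterol exporter Abca1 at -2.25. Fetal genes rose at 5 of 14 and fell at 3 (adjusted p = 0.24), and TGF-beta genes rose at 3 of 15 and fell at 5 (adjusted p = 0.6), with Cish at -5.89. Among markers, endothelial genes fell at 9 of 9 (adjusted p = 2.5e-05, and 0.022 with an estimated correlation) and type 2 genes at 9 of 10 (adjusted p = 0.0082, but 0.22 with an estimated correlation). Fibroblast genes fell at 7 of 10 with 1 rise (adjusted p = 0.021, but 0.2 with an estimated correlation) and B cell genes at 8 of 8 (adjusted p = 0.026, but 0.18 with an estimated correlation). Airway and type 1 genes fell at 7 of 11 and T and NK genes at 7 of 10, each with 1 rise (adjusted p = 0.13 and 0.062). Neutrophil genes fell at 6 of 12 with 1 rise (adjusted p = 0.24), dendritic cell genes at 6 of 8 with 2 rises (adjusted p = 0.33), erythroid genes at 2 of 5, or 0 with limma on log2(CPM + 1) (adjusted p = 0.51), eosinophil genes at 1 of 3 (adjusted p = 0.33) and sex-linked genes at 3 of 5 (adjusted p = 0.24).

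**Figure D1:**
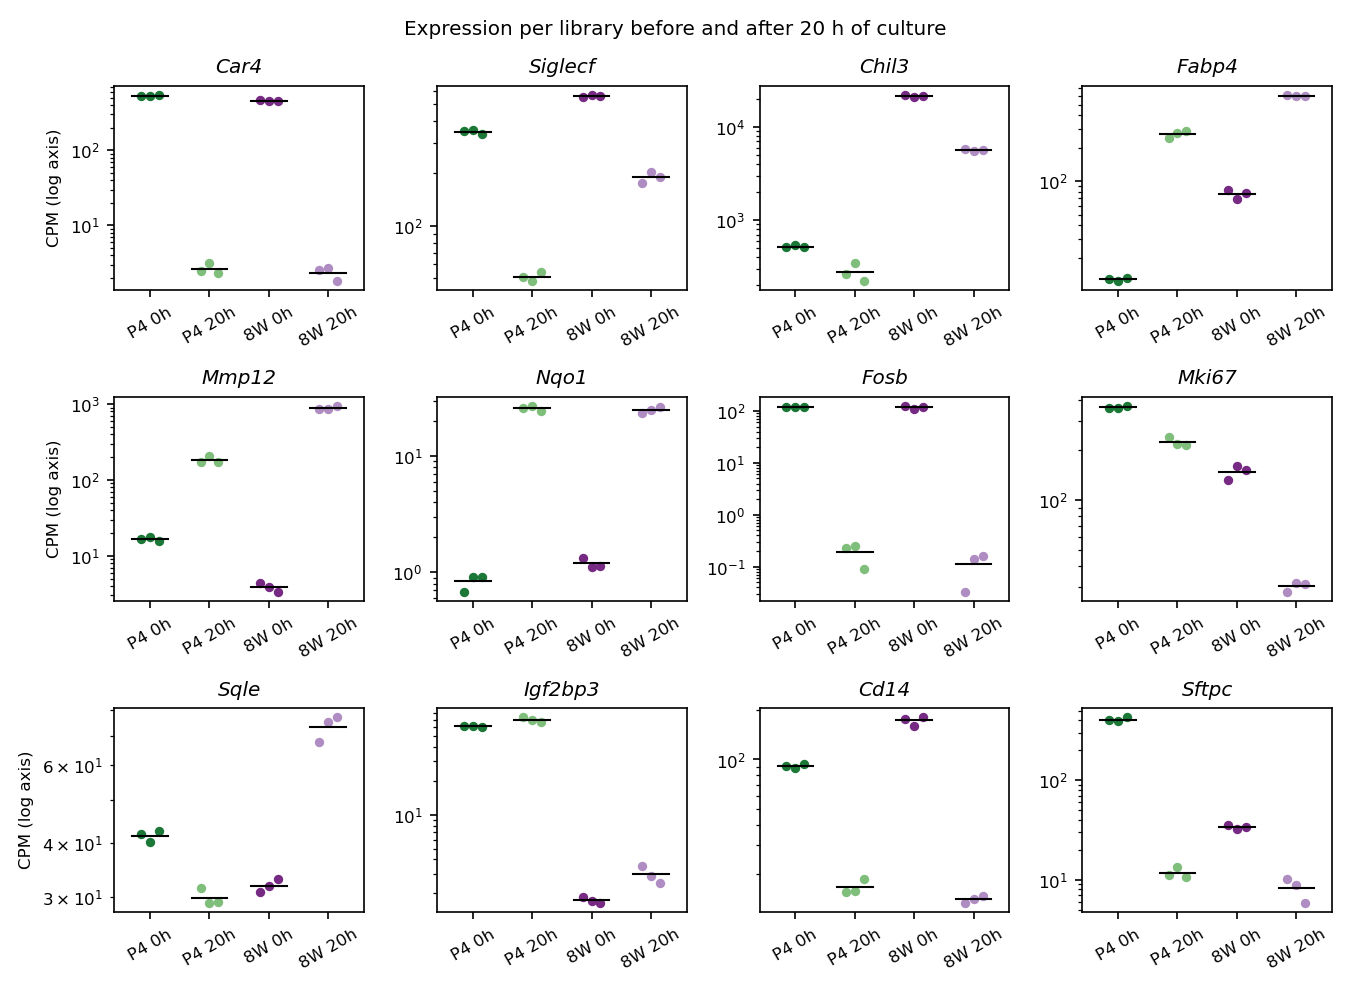
Expression of 12 genes in CPM on a log axis, with each point 1 library and the bar the mean of 3, for P4 and 8W cells at 0h and after 20h of culture. Car4 dropped from 528 to 2.64 CPM at P4 and from 458 to 2.34 at 8W, while Sqle rose to 73.3 at 8W and declined to 30 at P4.

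The 2 ages answered culture differently in part. Mki67 declined in P4 cells from 361 ± 4.09 to 223 ± 14.6 CPM and in adult cells from 148 ± 14.3 to 30.4 ± 1.96. Mmp8, a collagenase, rose at P4 from 10.2 ± 0.916 to 119 ± 4.63 CPM and declined at 8W from 30.4 ± 1.67 to 18.1 ± 1.26, and Abca1 rose from 62.4 ± 2.23 to 97.9 ± 6.91 at P4 and declined from 200 ± 23.6 to 42.1 ± 2.15 at 8W. By the difference of the culture effects (P4 minus 8W), edgeR called 5864 genes, 3320 with the higher response at P4 and 2544 with the lower, with 678 and 778 differing at least 2-fold. A higher response is a more positive log2 change, which can be a smaller fall, as for Mki67. The balance turned to 3352 higher and 3785 lower with limma on log2(CPM + 1), 2852 and 2927 with RLE factors, 2673 and 2828 with DESeq2, 2716 and 2775 without 8W 20h replicate 1, 2571 and 2577 without 8W 20h replicate 3, and 2701 and 2703 without P4 20h replicate 1. Across genes, which are not independent replicates, the log2 culture effects of the ages correlated with r = 0.740.

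Cholesterol biosynthesis genes responded lower at P4 at 20 of 23, with 1 the other way adjusted over the list alone and 0 over all genes (median -0.89, adjusted p = 1.4e-13, but 0.069 with an estimated correlation), such as Sqle (-1.67 ± 0.08 SE), Cyp51 (-1.52), Insig1 (-1.43) and Hsd17b7 (-1.96). Cell cycle genes responded higher at P4 at 29 of 35 and lower at 2, or 30 and 2 adjusted over the list alone (median 0.98, adjusted p = 7.3e-12, but 0.087 with an estimated correlation). Ccna2 differed by 1.75 and Top2a by 1.40. Most cell cycle genes fell at both ages, so this was mainly a smaller fall at P4. TLR signalling genes responded higher at 11 of 21 and lower at 2, or 12 and 2 adjusted over the list alone (median 0.47, adjusted p = 0.0039, but 0.069 with an estimated correlation): Tlr2 at 1.25, Cd14 at 1.18, Tlr7 at 1.07 and Tlr4 at 0.75. Cd14 fell at both ages, and less so at P4. Interferon-stimulated genes responded higher at 10 of 26, or 11 adjusted over the list alone, and lower at 0 (adjusted p = 0.023, but 0.72 with an estimated correlation), and NF-kB genes higher at 10 of 25 and lower at 4 (adjusted p = 0.032, but 0.44 with an estimated correlation), with the NF-kB inhibitor Nfkbia at 1.15. Identity genes responded lower at 13 of 30 and higher at 6, or 16 and 6 adjusted over the list alone (adjusted p = 0.03, but 0.37 with an estimated correlation). Krt79 differed by -3.05 and Siglecf by -1.22 but Chil3 by 1.02, while Pparg (0.17), Marco (-0.15) and Car4 (-0.01) were not called. Fetal genes responded lower at 8 of 14 and higher at 3 (median -3.26, or -3.06 with members that had a group at 0 set to a floor of 3 counts over the group, adjusted p = 6.4e-05, and 0.042 with an estimated correlation). The imprinted Mest differed by -4.96 and Peg3 by -4.48. Which cells the fetal transcripts at P4 0h came from was not measured, so a loss of other lung cells is not separated from a macrophage response. The endothelial genes Cd34 (3.35) and Kdr (3.15) responded higher at P4 by edgeR, which limma on log2(CPM + 1) reversed to -1.61 and -0.42.

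The remaining lists were not called by camera for the difference of the culture effects, apart from 4 lists of markers. Matrix genes responded lower at P4 at 8 of 19, or 9 adjusted over the list alone, and higher at 5 (adjusted p = 0.075), with Mmp12 at -4.37 and Mmp14 at -2.56. NRF2 genes responded higher at 4 and lower at 6 of 16, or 4 and 7 adjusted over the list alone (adjusted p = 0.53), and glycolysis genes higher at 3 and lower at 6 of 20, or 4 and 7 adjusted over the list alone (adjusted p = 0.1). Inflammatory cytokines responded higher at 9 of 19, or 10 adjusted over the list alone, and lower at 6 (adjusted p = 0.94). Immediate-early genes responded higher at 9 and lower at 8 of 23 (median -0.04, mean 0.14, adjusted p = 0.97), and MHC class II genes higher at 6 and lower at 5 of 12 (median 0.11, mean -0.23, adjusted p = 0.99). Phagocytic receptors responded higher at 6 and lower at 4 of 17, or 6 and 6 with limma on log2(CPM + 1) (adjusted p = 0.97). LXR targets responded higher at 6 and lower at 6 of 15 (adjusted p = 0.85). TGF-beta genes responded higher at 5 and lower at 4 of 15, or 5 and 6 with RLE factors and DESeq2 and 4 and 5 with limma on log2(CPM + 1) (median 0.07 but a downward test, adjusted p = 0.99). Interstitial macrophage genes responded higher at 5 and lower at 6 of 17 (median 0.37, or 0.21 at the floor, but a downward test, adjusted p = 0.58). Among markers, type 2 genes responded lower at 7 of 10 and higher at 1 (adjusted p = 0.00038, but 0.13 with an estimated correlation) and fibroblast genes lower at 3 of 10 (adjusted p = 6.4e-05, but 0.069 with an estimated correlation). B cell genes responded lower at 6 of 8, or 7 adjusted over the list alone (adjusted p = 0.00048, but 0.069 with an estimated correlation), and erythroid genes lower at 2 of 5 (adjusted p = 0.009, but 0.095 with an estimated correlation). Airway and type 1 genes responded lower at 4 of 11 and higher at 1 (adjusted p = 0.1), and sex-linked genes higher at 3 of 5 (adjusted p = 0.1). Directions turned with limma on log2(CPM + 1) for neutrophil genes (4 higher and 2 lower of 12, against 2 and 7, adjusted p = 0.97), endothelial genes (2 and 2 of 9, or 2 and 4 adjusted over the list alone, against 0 and 7, and 1 and 2 with DESeq2, adjusted p = 0.19) and T and NK genes (0 and 3 of 10, against 4 and 2, median -0.25 but an upward test, adjusted p = 0.85). They also turned for dendritic cell genes (1 and 1 of 8, against 1 and 3, adjusted p = 0.24) and eosinophil genes (0 and 0 of 3, against 0 and 3, adjusted p = 0.3).

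**Figure D2:**
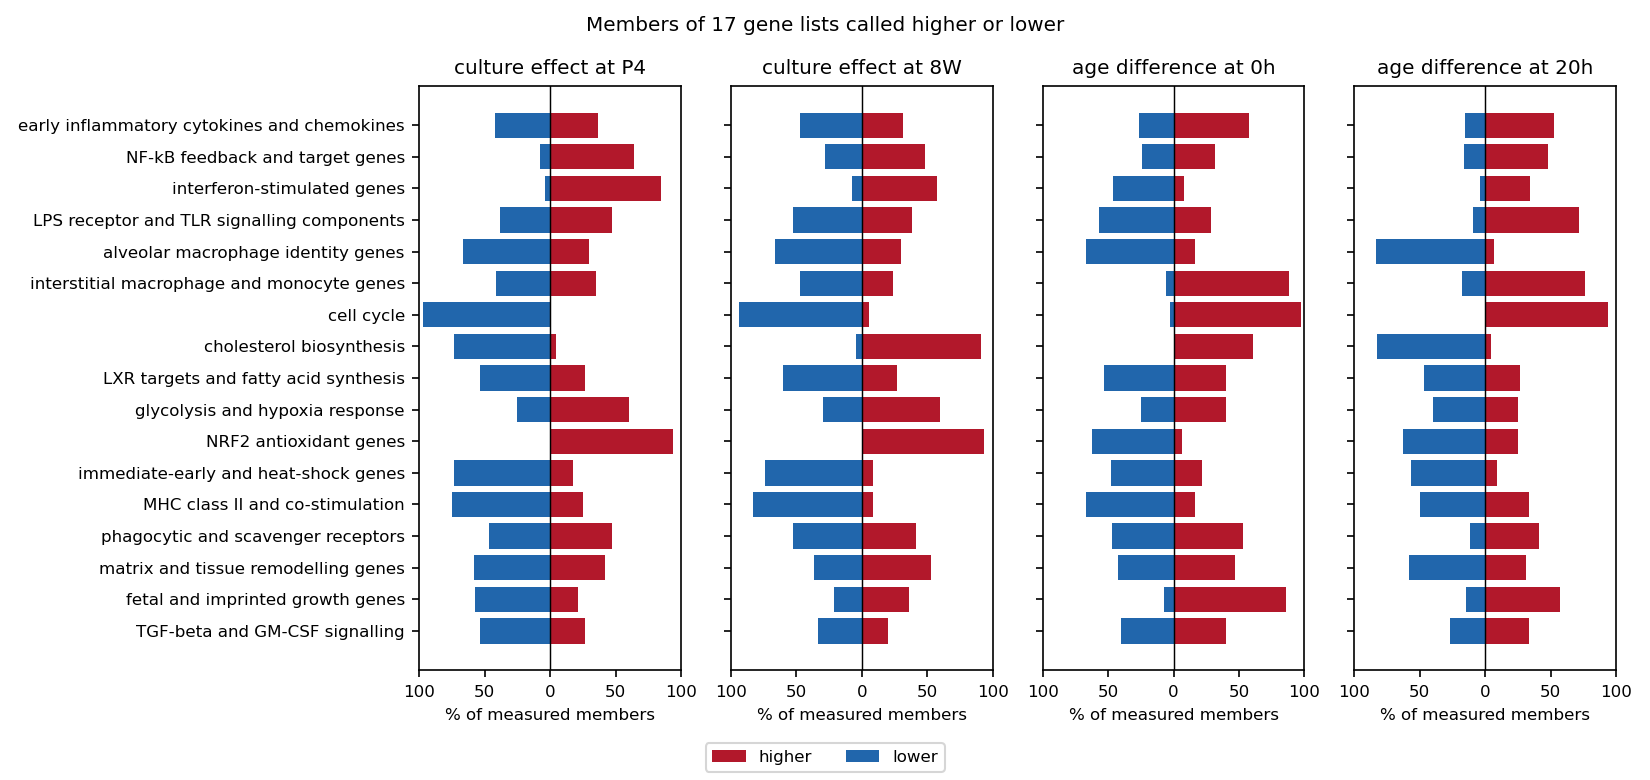
Bars give the percent of measured members of each of 17 gene lists called higher (right) or lower (left) by edgeR, for culture at P4, culture at 8W, and P4 against 8W at 0h and at 20h. Cholesterol biosynthesis shows 17 of 23 members lower in culture at P4 and 21 higher at 8W, and NRF2 antioxidant genes show 15 of 16 higher at both ages.

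At 0h P4 libraries had lower levels of some alveolar macrophage genes than adult ones and higher levels of fetal and proliferative ones. Of these 3 lists only the fetal one was also called with an estimated correlation. Which cells the fetal and proliferative transcripts came from was not measured. Chil3, a chitinase-like protein of adult alveolar macrophages, was at 21400 ± 331 CPM at 8W 0h and 521 ± 13.6 at P4 0h. Igf2bp3, a fetal RNA-binding protein, was at 60.9 ± 0.949 CPM at P4 0h and 1.74 ± 0.116 at 8W 0h. Apoe, a lipid carrier of macrophages, was at 260 ± 21.3 CPM against 27.3 ± 1.17. By edgeR 9173 genes were called, 4487 higher and 4686 lower at P4, with 2154 and 810 at least 2-fold. Genes higher at P4 made up 48.9% of them, but 54.1% with RLE factors, 54.8% with DESeq2 and 64.1% with limma on log2(CPM + 1).

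The largest differences at 0h under the naming rule were Xist (12.08 ± 0.23 SE), expressed from the inactive X chromosome of females, the matrix gene Tnc (8.94), Adamdec1 (8.03), Meg3 (7.71), Ldhb (7.05) and the haemoglobin gene Hba-a2 (6.70), and on the adult side Spag11b (-9.99), Hr (-6.82), Pnpla5 (-6.58), Ucp3 (-5.43), Chil3 (-5.36) and Ces2c (-5.36). Fetal and imprinted genes were higher at P4 at 12 of 14 and lower at 1 (median 5.26, or 5.02 at the floor, adjusted p = 6.4e-07, and 0.012 with an estimated correlation). Igf2bp3 differed by 5.13, Mest by 5.60 and Arid3a by 1.68. Cell cycle genes were higher at 34 of 35 and lower at 1 (median 1.16, adjusted p = 9e-15, but 0.058 with an estimated correlation). Birc5 differed by 1.45 and Mki67 by 1.29. Interstitial macrophage and monocyte genes were higher at 15 of 17 and lower at 1 (median 2.65, adjusted p = 7.6e-06, and 0.019 with an estimated correlation). The chemokine receptor Cx3cr1 differed by 4.35 and Ccr2 by 3.20, and which cells gave these transcripts was not measured. Identity genes were lower at 20 of 30 and higher at 5 (median -0.39, adjusted p = 7.6e-06, but 0.06 with an estimated correlation). Fabp1 differed by -3.69, Krt79 by -2.95 and Fabp4 by -2.58, and smaller differences of Siglecf (-0.68), Pparg (-0.29), Marco (-0.17) and Car4 (0.21). MHC class II genes were lower at 8 of 12 and higher at 2, or 3 adjusted over the list alone (median -1.01, adjusted p = 0.011, but 0.06 with an estimated correlation). The invariant chain Cd74 differed by -1.58 and the co-stimulator Cd80 by -1.83. Cholesterol genes were higher at 14 of 23 and lower at 0 (median 0.25, adjusted p = 0.0042, but 0.36 with an estimated correlation). Among single genes, the LPS co-receptor Cd14 (-0.93), Tlr4 (-0.58) and Tlr2 (-0.83) were lower at P4, as were Nfkbia (-1.04) and Tnfaip3 (-0.92), which restrain NF-kB, while Il1b (1.62) and Il1a (1.34) were higher.

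Camera made no call at 0h for 11 of the 17 lists. Inflammatory cytokines were higher at 11 of 19 and lower at 5 (adjusted p = 0.086), TLR genes higher at 6 of 21 and lower at 12 (median -0.24, mean 0.14, adjusted p = 0.25), and interferon-stimulated genes higher at 2 of 26 and lower at 12 (adjusted p = 0.096). NF-kB genes were higher at 8 of 25 and lower at 6 (mean 0.14 but a downward test, adjusted p = 0.99). NRF2 genes were higher at 1 of 16 and lower at 10 (adjusted p = 0.066), immediate-early genes higher at 5 of 23 and lower at 11 (adjusted p = 0.086), and glycolysis genes higher at 8 of 20 and lower at 5 (adjusted p = 0.32). LXR targets were higher at 6 of 15 and lower at 8 (median -0.14, mean 0.03, adjusted p = 0.32). Phagocytic receptors were higher at 9 of 17 and lower at 8 (adjusted p = 0.59), and matrix genes higher at 9 of 19 and lower at 8 (adjusted p = 0.51). TGF-beta genes were higher at 6 and lower at 6 of 15, or 7 and 4 with limma on log2(CPM + 1) (median 0.06 but a downward test, adjusted p = 0.99). Markers of other cells were higher at P4 for fibroblasts at 10 of 10 (median 4.65, adjusted p = 3.1e-07, and 0.019 with an estimated correlation) and type 2 cells at 10 of 10 (median 2.93, adjusted p = 1.7e-05, but 0.06 with an estimated correlation). Neutrophil genes were higher at 10 of 12 and lower at 1 (adjusted p = 0.00066, but 0.084 with an estimated correlation). Airway and type 1 genes were higher at 9 of 11, or 10 adjusted over the list alone, and lower at 1 (adjusted p = 0.0035, but 0.058 with an estimated correlation), and erythroid genes higher at 5 of 5 (adjusted p = 0.0025, but 0.06 with an estimated correlation). Endothelial genes were higher at 6 of 9 and lower at 2 (adjusted p = 0.28), eosinophil genes higher at 3 of 3 (adjusted p = 0.059), dendritic cell genes higher at 3 of 8 and lower at 2 (adjusted p = 0.41). T and NK genes were higher at 1 of 10 and lower at 4 (adjusted p = 0.19), B cell genes higher at 1 of 8 and lower at 4 (adjusted p = 0.7). Sex-linked genes were higher at 1 of 5 and lower at 4 (median -0.95, mean 1.57, adjusted p = 0.051). The X-linked Xist was between 0 and 0.0784 CPM in adult libraries and at 192 ± 9.16 at P4 0h, where the Y-linked Ddx3y was also present, between 29.5 and 31.9 CPM.

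After 20 h in the same medium the ages still differed, with cell cycle and interstitial macrophage genes higher and alveolar macrophage identity genes lower at P4. Whether alveolar macrophages or other macrophages and monocytes in the P4 libraries gave these differences was not measured. Mki67 was at 223 ± 14.6 CPM at P4 20h and 30.4 ± 1.96 at 8W 20h. Krt79, a keratin of adult alveolar macrophages, was at 1.07 ± 0.171 against 68.5 ± 5.67 CPM, and Cd74 at 34 ± 1.87 against 181 ± 14.4. Igf2bp3 was at 69.5 ± 3.44 against 2.95 ± 0.52. By edgeR 7210 genes were called, 3660 higher and 3550 lower at P4, with 1363 and 694 at least 2-fold. Genes higher at P4 made up 50.8%, but 65.4% with limma on log2(CPM + 1), 49.6% with DESeq2, and 46.8%, 47.2% and 47.6% without 8W 20h replicate 1, 2 or 3 and 47.7% without P4 20h replicate 1.

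Cell cycle genes were higher at P4 20h at 33 of 35 (median 2.13, adjusted p = 5.6e-24, and 0.033 with an estimated correlation), including Ccna2 (3.21 ± 0.08 SE), Birc5 (2.86) and Top2a (2.65). Interstitial macrophage genes were higher at 13 of 17 and lower at 3 (median 3.12, or 3.04 at the floor, adjusted p = 0.00035, and 0.033 with an estimated correlation). The complement gene C1qb differed by 5.51, Maf by 3.28 and Ccr2 by 2.64. Identity genes were lower at 25 of 30 and higher at 2 (median -0.53, adjusted p = 4.6e-13, and 0.033 with an estimated correlation). Krt79 differed by -5.99, Gpd1 by -4.66, Chil3 by -4.34, Ear1 by -2.67 and Siglecf by -1.90, while Car4 (0.19) and Pparg (-0.12) were not called. Cholesterol genes were lower at 19 of 23, or 20 adjusted over the list alone, and higher at 1 (median -0.85, adjusted p = 1.2e-10, but 0.074 with an estimated correlation). Hsd17b7 differed by -1.58 and Sqle by -1.29. Inflammatory cytokines were higher at 10 of 19, or 11 adjusted over the list alone, and lower at 3 (adjusted p = 0.015, but 0.24 with an estimated correlation). Il1b differed by 2.48. NF-kB genes were higher at 12 of 25 and lower at 4 (adjusted p = 0.015, but 0.31 with an estimated correlation). Birc3 differed by 0.92. TLR genes were higher at 15 of 21 and lower at 2, or 4 adjusted over the list alone (adjusted p = 0.0057, but 0.053 with an estimated correlation). Tlr9 differed by 3.33 and Tlr1 by 1.28. Immediate-early genes were lower at 13 of 23 and higher at 2 (adjusted p = 0.01, but 0.2 with an estimated correlation), and NRF2 genes lower at 10 of 16 and higher at 4 (adjusted p = 0.027, but 0.2 with an estimated correlation). Matrix genes were lower at 11 of 19, or 12 adjusted over the list alone, and higher at 6 (adjusted p = 0.047, but 0.2 with an estimated correlation). The cytokine Spp1 differed by -1.63. Fetal genes were higher at 8 of 14, or 9 adjusted over the list alone, and lower at 2 (median 2.03, or 1.75 at the floor, adjusted p = 0.011, but 0.053 with an estimated correlation). MHC class II genes were lower at 6 of 12, or 7 adjusted over the list alone, and higher at 4 (adjusted p = 0.073), although H2-Ab1 (-3.37), H2-Aa (-3.19) and Cd74 (-2.41) differed widely.

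Of the other lists at 20h, phagocytic receptors were higher at P4 at 7 of 17 and lower at 2 (adjusted p = 0.073), with the scavenger receptor Msr1 at 1.51 but Cd36, a receptor for oxidised lipid, at -1.69. Interferon-stimulated genes were higher at 9 of 26 and lower at 1 (adjusted p = 0.41), and TGF-beta genes higher at 5 of 15 and lower at 4 (median 0.01 but a downward test, adjusted p = 0.96). LXR targets were higher at 4 of 15 and lower at 7 (median -0.04, mean 0.13, adjusted p = 0.53), with Apoe at 4.39 and Scd1 at -3.88. Glycolysis genes were higher at 5 of 20 and lower at 8 (median -0.05, mean 0.32, adjusted p = 0.32). Neutrophil genes were higher at P4 at 12 of 12 (median 3.81, or 3.01 at the floor, adjusted p = 1.8e-07, and 0.033 with an estimated correlation), although 3 of the 12 were also at 5 CPM or more at 8W 20h. Fibroblast genes were higher at 7 of 10 (median 4.32, adjusted p = 0.00036, but 0.053 with an estimated correlation), with only 1 of them at 5 CPM or more at P4 20h. B cell genes were lower at 6 of 8 and higher at 1 (adjusted p = 0.0043, but 0.053 with an estimated correlation), and sex-linked genes lower at 4 of 5 and higher at 1 (median -0.66, mean 1.98, adjusted p = 0.047, but 0.21 with an estimated correlation). Type 2 genes were higher at 3 of 10 and lower at 1 (adjusted p = 0.59), airway and type 1 genes higher at 6 of 11 and lower at 2, or 3 adjusted over the list alone (adjusted p = 0.13), and erythroid genes higher at 3 of 5 (adjusted p = 0.13). Endothelial genes were higher at 2 of 9 and lower at 2 (adjusted p = 0.46), and T and NK genes higher at 1 of 10 and lower at 3, or 4 adjusted over the list alone (adjusted p = 0.15). Eosinophil genes were higher at 2 of 3 (adjusted p = 0.16), and dendritic cell genes higher at 1 of 8 and lower at 1 (median 0.20, or 0.21 at the floor, but a downward test, adjusted p = 0.98).

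Age differences of the 0h libraries were partly kept in culture. Genes higher at P4 at both times numbered 2130 and genes higher at 8W at both times 2024, where 1030 and 1044 would be expected for unrelated calls. Over the 9173 genes called at 0h, the log2 age difference at 20h was 0.582 ± 0.056 (jackknife SE over 12 libraries) of that at 0h, between 0.556 and 0.608 with each library left out. Of these genes 4154 were called in the same direction at 20h and 961 in the opposite one. Among the 2964 with an age difference of at least 2-fold at 0h, 1623 were called in the same direction at 20h, 118 in the opposite one and 1223 not at all. With genes chosen on 1 library per age by a difference of at least 2-fold, and the 0h difference measured in the other 2, the share kept was 0.491. That value was taken on log2 CPM with a prior count of 2, over between 3166 and 3342 genes. Measure and genes thus changed along with the choice, whose own effect is not isolated. Over genes called at 0h with a mean CPM of at least 5 at 20h, the share by edgeR was 0.674. RNA of other lung cells at P4 0h that was lost by 20h may lower this share, and was not separated from macrophage expression. Of 2057 genes differing at least 2-fold at 20h, 1593 had the same sign at 0h, 357 were not called there and 107 had the opposite sign.

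Far fewer accessible regions were listed after culture. The ATAC-seq lists held 40120 peaks at P4 0h and 22346 at P4 20h, and 53273 at 8W 0h and 13297 at 8W 20h, covering 9.46, 6.01, 12.39 and 3.71 Mb. Most peaks of cultured cells overlapped a peak of the longer 0h lists: 88.8% (95% Wilson interval 88.4 to 89.2) of the P4 20h peaks overlapped a P4 0h peak, and 94.5% (94.1 to 94.9) at 8W. With lists of equal size these were 45.6% and 31.3%, where 0h peaks had to be drawn at random from 27337 (P4) and 40212 (8W) at the highest score, which lowers the shares by construction. In the other direction 50.1% (49.7 to 50.6) of P4 0h peaks and 24.0% (23.7 to 24.4) of 8W 0h peaks were found at 20h. At Car4 (chromosome 11, 84957754 to 84966054 in mm10) a peak within the gene was listed at 0h at both ages, from 84959906 to 84960188 at P4 and from 84959959 to 84960271 at 8W, and was not found at 20h. This gene's region was singled out after the lists had been seen. At P4, genes that rose at least 2-fold in culture had a peak of the 20h list not found at 0h within 20 kb more often (25.8%) than genes not called (14.4%, odds ratio 2.06, adjusted p = 6.1e-17 by Fisher's exact test). For all called genes the share was 19.7% for those that rose (odds ratio 1.45, adjusted p = 2.8e-11) and 16.2% for those that fell (odds ratio 1.14, adjusted p = 0.032). The latter was not called at 100 kb (1.06) or within groups of span (1.05). At 8W the shares were 6.4% for genes that rose and 5.9% for genes that fell against 5.4% (adjusted p = 0.077 and 0.4 by Fisher's exact test). This depended on the setting, since a reciprocal overlap of 50% (odds ratios 1.32 and 1.28) gave calls for both, and 100 kb (1.27) for genes that rose. Peaks of 0h not found at 20h lay near genes of both directions: near 70.9% of genes that rose and 71.9% of genes that fell at P4 against 65% of genes not called, and near 87.8% and 85.7% against 76.5% at 8W.

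How far neonatal and adult peak lists overlapped depended on the settings. At 0h 89.1% of P4 peaks overlapped an adult peak and 67.2% of adult peaks a P4 peak. At 20h 52.1% of P4 peaks overlapped an adult peak and 87.2% of adult peaks a P4 peak. With lists of equal size, where the same random draw lowers the shares at 0h, 31.1% overlapped each way at 0h, and 73.5% of P4 and 73.6% of adult peaks at 20h. After PBS in vivo, 67.4% of 30952 P4 peaks overlapped an adult peak and 83.5% of 24986 adult peaks a P4 peak, and after LPS 69.9% of 21916 and 75.8% of 20205. Genes at least 2-fold higher in adults at 0h had an adult peak without a P4 counterpart more often (75.4%) than genes not called (56%, odds ratio 2.41, adjusted p = 3.9e-23 by Fisher's exact test). The 8W 0h list had such a peak at Chil3, from 106144005 to 106144504 on chromosome 3, a position singled out after the lists had been seen. Genes higher at P4 at 0h had a P4 peak without an adult counterpart more often (35% against 28.1%, odds ratio 1.38). This turned to an odds ratio of 0.89 with equal-sized lists, drawn in part at random. At 20h genes at least 2-fold higher at 8W had an adult-specific peak more often (22.1% against 14.9%, odds ratio 1.61). P4-specific peaks at 20h lay near genes of both directions, near 61% of genes higher and 57.4% of genes lower at P4 against 49.3% of genes not called (odds ratios 1.61 and 1.39), and near 51.6% of genes at least 2-fold higher at P4 (odds ratio 1.1, or 1.26 and called at 5 kb).

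**Figure D3:**
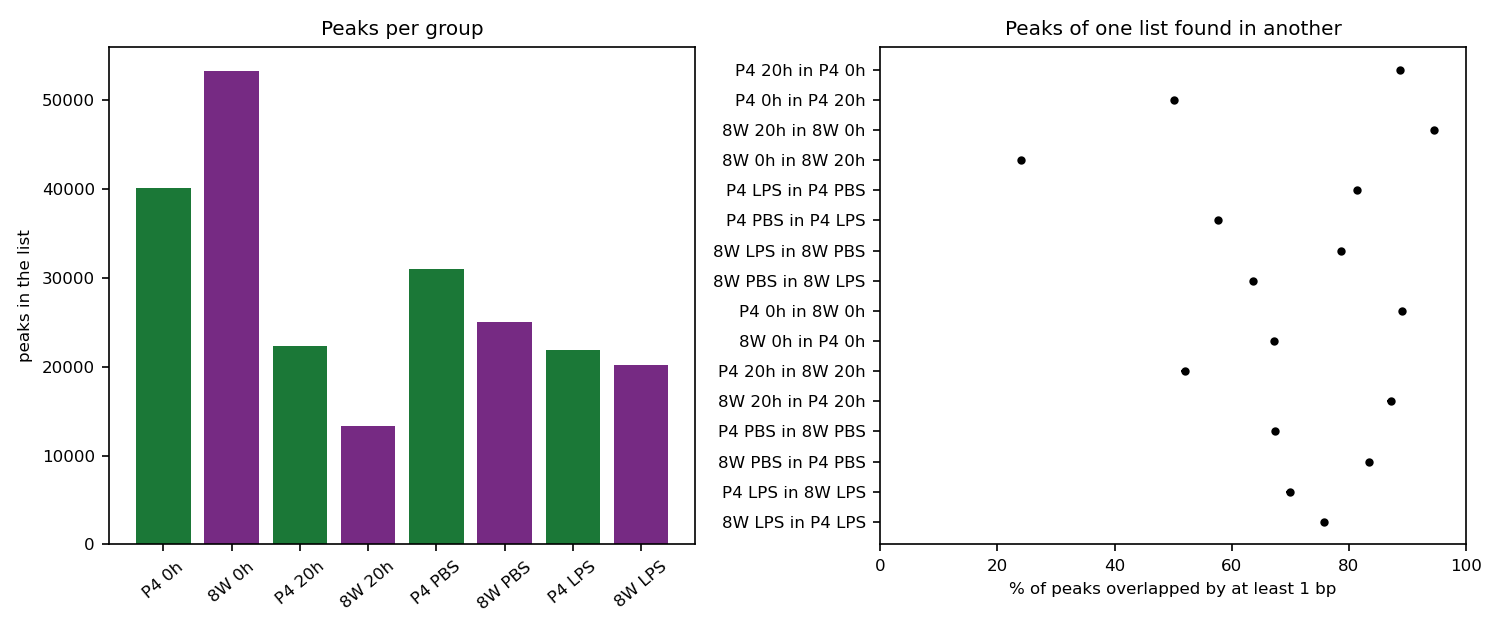
Bars (left) give the number of peaks in each of the 8 ATAC-seq lists, each from 2 libraries, and points (right) the percent of the peaks of 1 list found in another, with 95% Wilson intervals narrower than the points. The 20h lists hold 22346 (P4) and 13297 (8W) peaks against 40120 and 53273 at 0h.

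After LPS for 2 h many NF-kB and cytokine genes had a nearby peak not listed after PBS. No gene list stood out after adjustment from random lists matched in part on those same peaks. P4 LPS peaks overlapped P4 PBS peaks at 81.4%, leaving 4075 without a PBS counterpart, and 8W LPS peaks overlapped 8W PBS peaks at 78.7%, leaving 4302. In the other direction 57.7% of P4 PBS peaks and 63.7% of 8W PBS peaks were found after LPS. Of 25 NF-kB feedback and target genes, 18 had an LPS peak without a PBS counterpart within 20 kb at P4 and 18 at 8W (72% against 25% and 27.3% of other genes, adjusted p = 7.2e-05 and 0.00014 by Fisher's exact test over 68 tests). Inflammatory cytokines had one at 12 of 19 at P4 and 13 of 19 at 8W (adjusted p = 0.0066 and 0.0038 by Fisher's exact test), and immediate-early genes at 9 and 16 of 23 (adjusted p = 0.33 and 0.00067). MHC class II genes had one at 8 of 12 at 8W (odds ratio 5.32, adjusted p = 0.039), which turned to an odds ratio of 0.73 with equal-sized lists, drawn in part at random. Identity genes had a PBS peak missing from the LPS list near 25 of 30 at P4 and 23 of 30 at 8W (adjusted p = 0.039 and 0.018). They had an LPS peak without a PBS counterpart near 15 of 30 at P4 (adjusted p = 0.039). Interferon-stimulated genes had an LPS-specific peak at 3 of 26 at P4 and 10 of 26 at 8W (adjusted p = 0.36 and 0.47). Genes with many differing peaks nearby are favoured by such counts. Among 10000 random lists matched for that, the median number of genes with a peak was 11 at P4 and 12 at 8W in place of the 18 NF-kB genes (permutation p = 0.0024 and 0.0062), and 9 and 10 in place of the 12 and 13 cytokine genes (permutation p = 0.061 and 0.049). No list passed adjustment against matched lists (lowest adjusted p = 0.16 by permutation). The matching counted LPS-specific peaks too, so it took up part of any LPS effect. The lack of a call therefore does not show that there was none. Near Nfkbia (chromosome 12, 55489409 to 55492647) an LPS-specific peak lay at 55487847 to 55488118 at P4 and at 55487797 to 55488113 at 8W, and near Cxcl2 on chromosome 5 at 90906664 to 90906940 and 90906512 to 90906750. These positions were singled out after the lists had been seen.

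**Figure D4:**
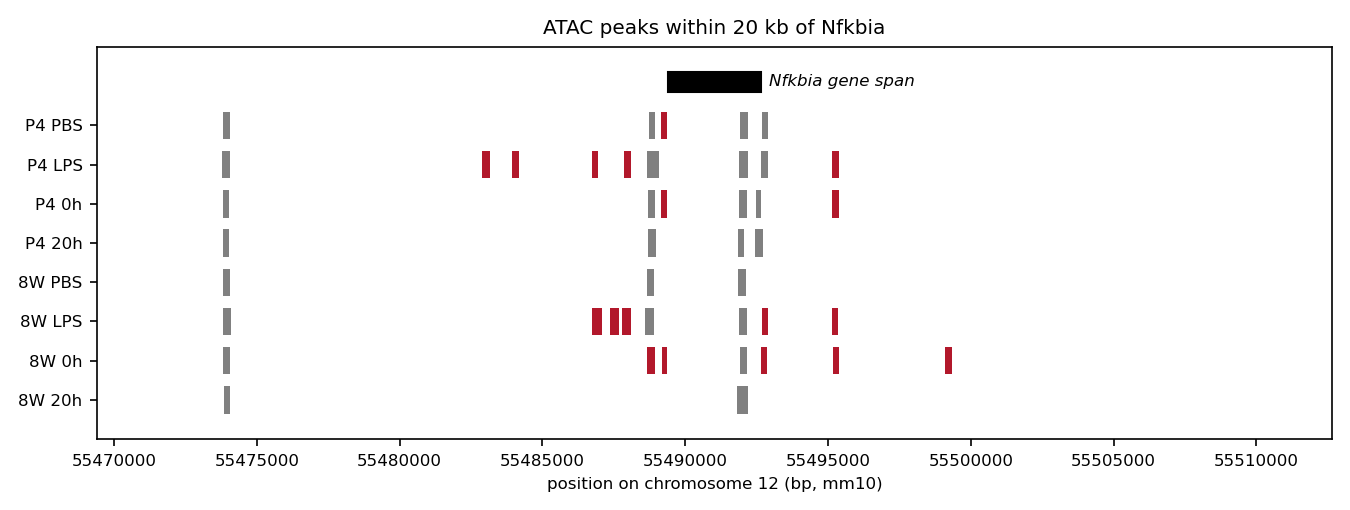
Peaks of the 8 ATAC-seq lists around Nfkbia on chromosome 12 in mm10 coordinates, with the gene in black, red for a peak without overlap in its partner list (LPS and PBS, or 20h and 0h, of the same age) and grey for the others. Red peaks of the LPS lists lie at 55487847 to 55488118 at P4 and at 55487797 to 55488113 at 8W, beside the gene.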

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

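The values in the first paragraphs stand out because the response to 20 h of culture differed between P4 and 8W, each tested as a difference of 2 culture effects by edgeR (P4 minus 8W, log2, 3 libraries per group). Groups of 3 libraries were not searched for single outlying samples. Among the tests that follow, the one on lost RNA behind the cholesterol genes was written after its result had been seen, the others before, and the fit on log2(CPM + 1) was added after the data were seen.

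The difference was called at 5864 genes. Of 100 splits of the libraries that permuted age within each culture time (200 are possible), 2 called as many, the real one and the one that swaps the ages at 1 time, which called 9124. That swapped split turns the shared effect of age into a difference, and without it the highest was 4057. It was put into the draw on purpose after a first draw without it had given 1 of 100. For each 2-group comparison the 10 splits of the 6 libraries are too few for a share under 0.05. The real one called 10475 genes for culture at P4, 9757 at 8W, 9687 for age at 0h and 6018 at 20h, the others 0. Splits that mix groups put their difference within a group, which lowers the calls, so no count here decides on chance.

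In the cell cycle list (median 0.98), Top2a differed by 1.40, Ccna2 by 1.75, Birc5 by 1.41 and Mki67 by 1.59. In the TLR list (median 0.47), Tlr7 differed by 1.07, Tlr2 by 1.25, Cd14 by 1.18, Ticam2 by 0.81 and Tlr4 by 0.75. Among interferon-stimulated genes (median 0.72), Trim30a differed by 0.78, Ifih1 by 0.67, Ddx58 by 0.70 and Ifit3 by 3.20. Among NF-kB genes (median 0.26), Ier3 differed by 1.98, Birc3 by 0.92, Irak3 by 0.77 and Nfkbia by 1.15. Among cytokines, Il1rn differed by -1.68, Il1a by -1.57, Ccl9 by -1.45 and Ccl3 by 0.99.

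In the identity list (median -0.17), Ear1 differed by -2.06, Krt79 by -3.05, Lpl by -1.10, Siglecf by -1.22, Mcoln3 by 0.93, Fabp4 by 1.44 and Chil3 by 1.02. Of monocyte and interstitial macrophage genes, Ace differed by -0.88, Plac8 by -3.79 and Ms4a7 by 1.01. Of MHC class II and co-stimulation genes, H2-Aa differed by -1.67, H2-Eb1 by -2.06, Cd80 by 1.65 and Ctss by 0.75. Of phagocytic receptors, Itgam differed by -2.31, Cd36 by -1.41, C5ar1 by 1.48 and Fcgr2b by 2.16. Of matrix genes, Mmp12 differed by -4.37, Mmp14 by -2.56, Plau by -1.64 and Spp1 by -1.46.

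In the fetal list (median -3.26, or -3.06 at the floor of 3 counts over the group), Hmga1 differed by -1.01, Mest by -4.96, Peg3 by -4.48 and Igf2bp3 by -0.56. Which cells these transcripts came from was not measured. Of LXR targets, Mylip differed by 1.77, Abca1 by 2.90, Scd1 by -3.36 and Scd2 by -1.04. Of glycolysis genes, Slc2a1 differed by -1.56, Pfkp by 0.71, Pgam1 by -0.63 and Eno1 by -0.55. Of NRF2 genes, Txnrd1 differed by -0.32, Gclm by -0.44, Srxn1 by -0.33 and Gclc by -0.31. Of immediate-early and heat-shock genes, Egr2 differed by -1.41, Btg2 by 0.93, Dusp1 by 1.03 and Hspa8 by -0.38. Of TGF-beta and GM-CSF genes, Cish differed by 2.71, Stat5a by 0.59, Rgcc by -1.0 and Stat5b by 0.30.

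Besides Mest and Abca1, the single genes named for the size of their difference were Mmp8 (4.29), Dnah11 (4.25), Arap3 (3.36), Cd34 (3.35) and Kdr (3.15), and on the other side Adamdec1 (-6.10), Lgi3 (-5.11), Vsig8 (-4.60), Fabp7 (-4.43) and Fam20c (-4.39). Cd34 and Kdr turned to -1.61 and -0.42 with limma on log2(CPM + 1), and stood at a mean of 0.00905 and 0.0476 CPM at 8W 20h. Marker lists also differed, with a median of -2.87 for type 2 cells, -0.58 for fibroblasts, -2.07 for B cells and -3.26 for erythroid cells, or -4.08 at the floor for the erythroid genes. With an estimated correlation camera called only the fetal list for the difference (adjusted p = 0.042), so the other 10 lists given with a median here lost the calls they had with a preset correlation. Dnah11, Cd34, Kdr, Adamdec1, Lgi3, Mest and Peg3 had an SE of at least 0.46.

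Cholesterol biosynthesis was the list with the smallest adjusted p for a difference between the ages in its response to culture (median -0.89) with a preset correlation, but was not called with an estimated one (adjusted p = 0.069), with Sqle at -1.67, Cyp51 at -1.52, Insig1 at -1.43 and Hsd17b7 at -1.96. Scaling is argued against, since under each of the 4 scalings tried (TMM, RLE, DESeq2 and plain library totals) at least 20 of 23 members were called lower. Within an age, 21 members rose at 8W and between 17 and 18 fell at P4 with TMM, RLE and DESeq2. With plain library totals 15 rose at 8W and 21 fell at P4. That fit was limma on log2(CPM + 1), so the test and the added 1 CPM differ as well as the scaling. RNA of other lung cells lost from the P4 libraries is argued against as the whole cause, since 19 of 23 members were lower at P4 than at 8W at 20h, where markers of those cells were low. A lower demand or a weaker sterol response of neonatal cells in this medium may be a candidate, but was not tested. A batch or a mix of sexes that follows age cannot be told apart from it.

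Many genes were higher at P4 than at 8W at 0h (2154 at least 2-fold), while fibroblast and type 2 markers were high in the same libraries, and 17 of 20 of these markers lay at P4 20h under 0.25 of their P4 0h level. Of the genes at least 2-fold higher at P4, 2081 had a known chromosome, and 3.8% of them lay on X or Y (Clopper-Pearson 95% interval 3.1 to 4.8). Among all tested genes the share was 3.4%, so genes on X or Y were not the main source. Too few tested genes lie there to have made up most of the 2081. The outcome was thus fixed beforehand and does not weigh on a mix of sexes at P4. Nor does it cover genes on other chromosomes that differ by sex. Xist was at most 0.0784 CPM in adult libraries and high at P4, so an effect of sex on such genes cannot be told apart from age. For 1019 genes not called higher at P4 at 20h, 66.9% (63.9 to 69.8) fell at least 4-fold in culture at P4, as RNA of lost cells would. Genes that macrophages themselves turn down would pass this test too, and the genes were chosen in part by that fall, so both explanations stay open. For 995 genes at least 2-fold higher at both times, 51.2% (48.0 to 54.3) held at least 0.5 of their P4 0h CPM, which does not decide between macrophage expression and other cells that survived culture.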

How the results depend on the processing

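The fits of limma on log2(CPM + 1), genes with a mean CPM of at least 5 at 20h, genes chosen on 1 library per age, gene classes of at least 2-fold near peaks, genes grouped by span, and all tests of peaks after LPS were chosen after the data were seen. No paired analysis was possible because the columns carry no replicate number, so a replicate block was not run. Also not run were the in vivo contrasts (LPS effects, age after PBS or LPS, the age difference in 2 experiments, the LPS response by age, and the share kept by genes called after PBS), and motif content. The planned limma fit on log2(TPM + 1) was run and its result seen, then left out and replaced by the one on log2(CPM + 1).

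Over the other fits, factors and filters and the libraries left out, the number of called genes lay between 7803 and 11355 for culture at P4, 8007 and 10801 for culture at 8W, 5057 and 7137 for the difference of the culture effects, 6686 and 9700 for age at 0h, and 5782 and 7265 for age at 20h. With each library left out they ran from 9986 to 10493, 9806 to 10085, 5148 to 5760, 8385 to 8680 and 6461 to 6907. Genes with a mean CPM of at least 5 at 20h (9847) gave 7199, 7406, 4719, 6134 and 5314 calls in the same order, outside these ranges, and by construction fewer genes were tested. Of the single genes named, 5510 values kept direction and side of the threshold, 12 lost a call, 10 gained one and 3 reversed: with limma on log2(CPM + 1), Smad2 in culture at 8W gave -0.045, and the difference of the culture effects gave -1.61 for Cd34 and -0.42 for Kdr. At 8W 20h Cd34 and Kdr stood far below the 1 CPM added before the log, which makes such falls smaller. No cause was tested for Smad2. Marco and Pparg for the difference of the culture effects gained a call without P4 20h replicate 1 (-0.18 and 0.24), and Marco also without 8W 0h replicate 3 (-0.18), 8W 20h replicate 1 (-0.21) and 8W 20h replicate 2 (-0.18). Marco also gained it with RLE factors (-0.19), DESeq2 (-0.19), a filter at a CPM of 5 (-0.17) and limma on log2(CPM + 1) (-0.17). Pparg gained a call for age at 20h without P4 20h replicate 2 (-0.19), and Marco lost one for age at 0h with limma on log2(CPM + 1) (-0.06). For age at 20h, Tlr4 lost its call with only the 2 groups (0.18), without 8W 20h replicate 2 (0.115) or 3 (0.14), and without P4 20h replicate 1 (0.16) or 2 (0.12). Cd14 lost it without 8W 20h replicate 1 (0.19) or 2 (0.23) and P4 20h replicate 3 (0.16), and Trim30a without 8W 20h replicate 2 (0.22) and P4 20h replicate 1 (0.23) or 2 (0.215).

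The share of the age difference kept in culture (0.582) moved to 0.505 with DESeq2, 0.472 with no low-count filter, 0.715 with a filter at a CPM of 5, 0.474 with limma on log2(CPM + 1), 0.685 for genes with a mean CPM of at least 5, 0.674 for genes with a mean CPM of at least 5 at 20h, and 0.491 for genes chosen on 1 library per age. It rose in the 3 settings that left out genes of low CPM. The setting with genes chosen on 1 library per age also changed the measure, to log2 CPM with a prior count of 2. With an estimated correlation camera called 4 lists for culture at P4, 2 for culture at 8W, 1 for the difference of the culture effects, 3 for age at 0h and 4 for age at 20h. Fry, which asks only whether a list moves on balance, called 27 for culture at 8W, 21 for the difference, 25 for age at 0h and 25 for age at 20h.

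Shares of overlapping peaks depended on the settings, in 45 of 48 cases by more than counting error. At an IDR of 0.01 P4 20h peaks were found in P4 0h at 91.9% and 8W 20h in 8W 0h at 96.4%, the reverse at 48.5% and 20.5%. There P4 LPS peaks were found in P4 PBS at 83.6% and the reverse at 54.8%, 8W LPS in 8W PBS at 79.6%, P4 0h in 8W 0h at 92.4% and the reverse at 65.3%, 8W 20h in P4 20h at 91.0%, P4 PBS in 8W PBS at 68.6% and the reverse at 84.6%, and P4 LPS in 8W LPS at 73.1% and the reverse at 74.1%. At a reciprocal overlap of at least 50%, P4 20h peaks were found in P4 0h at 81.9% and the reverse at 45.6%, 8W 20h in 8W 0h at 83.7% and the reverse at 20.9%. P4 LPS peaks were then found in P4 PBS at 77.8% and the reverse at 55.1%, and 8W LPS in 8W PBS at 75.5% and the reverse at 61.1%. P4 0h peaks were found in 8W 0h at 87.2% and the reverse at 65.6%, P4 20h in 8W 20h at 46.9% and the reverse at 78.8%, P4 PBS in 8W PBS at 65.5% and the reverse at 81.1%, and P4 LPS in 8W LPS at 67.2% and the reverse at 72.8%. Lists of equal size, cut at 13297 peaks with ties at random, gave 45.6% for P4 20h in P4 0h and 45.9% in reverse, 31.3% for 8W 20h in 8W 0h and 31.4% in reverse, 57.8% for P4 LPS in P4 PBS, and 66.9% for 8W LPS and PBS each way. They gave 31.1% for P4 0h and 8W 0h each way, 73.5% for P4 20h in 8W 20h and 73.6% in reverse, 59.9% for P4 PBS and 8W PBS each way, and 73.5% for P4 LPS in 8W LPS and 73.4% in reverse. At 0h many peaks share the highest score and the equal-sized lists draw from them at random, which lowers these shares by construction.

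Odds ratios for peaks near changed genes kept direction and side of the threshold in 129 of 160 cases. Equal-sized lists say little here, since the random draw among tied 0h peaks leaves many peaks without a partner by construction (7233 of 13297 at P4 20h). With them 5 turned: for P4 20h peaks not in 0h, to 0.96 near genes that fell and 0.98 near genes that rose at least 2-fold, and for P4 0h peaks not in 8W 0h, to 0.89 near genes higher at P4, 1.23 near genes lower and 0.54 near genes at least 2-fold higher. P4 0h peaks not in 20h near genes that fell at least 2-fold turned to 1.20 at 5 kb, and gained a call at 100 kb (0.75) and with a reciprocal overlap of 50% (0.88). Those near genes that rose at least 2-fold gained a call at 5 kb (1.33) and 100 kb (1.34). For P4 20h peaks not in 0h, the call near genes that fell was lost within groups of gene span (1.05) and at 100 kb (1.06), and near genes that fell at least 2-fold a call was gained within groups of span (0.78), at 100 kb (0.84), with a reciprocal overlap (0.77) and with equal-sized lists (0.51). For 8W 20h peaks not in 0h, calls were gained near genes that rose at 100 kb (1.27), with a reciprocal overlap (1.32) and with equal-sized lists (1.66), near genes that fell with a reciprocal overlap (1.28) and equal-sized lists (1.32), and near genes that fell at least 2-fold with equal-sized lists (0.69). For 8W 0h peaks not in 20h near genes that fell at least 2-fold the call was lost within groups of span (1.07) and at 100 kb (1.08). For age at 0h, a call was gained within groups of span near genes lower at P4 for P4 peaks (0.91) and near genes higher at P4 for adult peaks (0.88), and lost near genes at least 2-fold higher at 100 kb (1.01). For age at 20h and P4 peaks, calls were gained near genes at least 2-fold higher at 5 kb (1.26) and near genes at least 2-fold lower within groups of span (0.81), with a reciprocal overlap (0.83) and with equal-sized lists (0.76). After LPS at P4 the call near NF-kB genes was lost at 100 kb (3.05), and at 8W the odds ratio near MHC class II genes turned to 0.73 with equal-sized lists. For the other settings the cause was not tested. The depth of the ATAC-seq libraries is unknown, which limits each of these shares.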

Other observations

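Cish and Socs2, targets of GM-CSF signalling, fell in culture at both ages, Cish by 3.18 at P4 and 5.89 at 8W and Socs2 by 2.98 and 3.47, while Csf1r, the receptor of M-CSF, rose by 0.83 and 1.17 (log2, edgeR). Fabp4 stood at 12.9 ± 0.356 CPM at P4 0h and 76.8 ± 7.15 at 8W 0h, and at 271 ± 22.2 and 597 ± 8.38 at 20h (n = 3 each), a rise in a list of which 20 of 30 members fell at each age.

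Epcam, an epithelial marker, stood between 41.5 and 45.3 CPM at 8W 0h and between 4.23 and 5.4 at P4 0h, against its list, of which 9 of 11 members were higher at P4 at 0h. The granule gene Ngp fell from between 2.53 and 4.12 CPM at P4 0h to between 0.607 and 1.23 at P4 20h, and was 0 at 8W. S100a8 rose in culture at both ages, while S100a9 fell at P4. P4 libraries held both Xist and the Y-linked Kdm5d (between 17.9 and 18.9 CPM at P4 0h, against 40.2 and 41.2 at 8W 0h), as a mix of sexes would give.

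The test on elements that closed was written after its result had been seen, and the other before. Both ages listed fewer ATAC-seq peaks at 20h than at 0h. Closing of elements near genes that fell is left open. The share of genes with a 0h peak not found at 20h was, for genes that fell less those that rose at least 2-fold, -2.9 percentage points at P4 (95% Wald interval -6.4 to 0.5) and -8 at 8W (-10.6 to -5.5), and over all called genes 1 (-0.8 to 2.7) at P4 and -2.1 (-3.4 to -0.8) at 8W. Against genes not called, the odds ratio at 8W was 1.21 for genes that fell and 2.22 for genes that rose at least 2-fold, the first with no call within groups of span (1.07) or at 100 kb (1.08). A lower depth or quality of the 20h libraries remains a candidate, in line with the 0h peaks found again at 20h, which carried the highest score more often than those not found, by 30.4 points at 8W (98.6% against 68.2%) and 46.3 at P4. Stronger elements that stay open in living cells would give the same, so culture itself stays open too.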
